A study of Mus musculus with 6 samples.

How the data were processed

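Bone marrow of 3 mice carrying NPM1c-driven human AML was sorted into bulk and LSC populations, which gave 6 libraries, per the labels. RNA was amplified with a NuGEN Ovation kit before library preparation, per the labels' protocols. The submitters' processing notes name RSEM, Bowtie2, edgeR and the genome build hg19, with no version, order or role. The organism label names mouse, the host, while the gene symbols and the build are human. One table of the whole series was used. The authors' deposited sample values are log2 CPM, that is, log2 of reads scaled to a normalized library size with a small prior added. The scale was read from the values, since all 6 columns share 1 floor (0.0197 CPM, or 0.25 reads in a library of mean size) and rise above it in whole steps. The same deposited table holds the authors' log2 fold change, average log2 CPM, likelihood ratio score, p-value and false discovery rate per gene, per the file headers. The authors' fold change is coded bulk minus LSC, and their values were used only where the text names that table. Whether the authors' model contained the mouse is not given in the sources used here, nor is the rule by which low genes were left out.

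Subtracting the floor and dividing by the step gave reads per gene, whole within 0.1 for 100% of values. Total reads were 11420127, 11753494 and 13148257 in bulk replicates 1, 2 and 3 and 14933494, 11220753 and 10669560 in LSC replicates 1, 2 and 3. The authors' normalized library sizes were 5840753, 11807858, 15630850, 13532895, 15773981 and 13711393 in the same order, so bulk replicate 1 was the shallowest, and 51 to 262 genes per library had no read. RSEM values may have been rounded before deposit, so these reads are estimates. Amplified reads without molecular identifiers are not independent molecules, and counting intervals and floors cover counting error only. No 2 libraries were alike within sampling noise, with a chi-square per degree of freedom of 70.4 to 374 over all pairs. All 6 sample columns matched a library label.

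Genes with at least 1 CPM in at least 3 libraries were tested, which kept 13755 of 13892 and removed 137. LSC and bulk were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with trend, two-sided) on the deposited log2 values as they stood, with Benjamini-Hochberg adjustment and a threshold of 0.05. The design written before the data were examined named log2(CPM + 1) or deposited log2 values as they stand, and no block. Since the files hold log2 values, no count model was fitted, and edgeR and DESeq2 were not used here. Gene lists, 34 in number, were fixed at the same point. The 33 with at least 5 tested members were tested with camera at an inter-gene correlation of 0.01, with an estimated correlation, and with fry. The list of mitochondrially encoded genes had 0 members in the table. Counts of members that passed are given over all genes tested and adjusted over the list alone. Named genes are IL3RA, CD33 and NPM1, the 12 largest changes in each direction among genes past the threshold, and up to 4 members of each described list with the largest moderated statistic. Left out of the 12 were genes whose presence or level can identify a person, immunoglobulin and T cell receptor segments, and rows without a symbol. Other names were chosen after their values were seen and are said to be so. Some genes that the rule names are not reported here. In the table, 21 symbols had turned into dates and could not be matched, and no coordinates are given because the reference at hand is of another species.

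Fold changes of genes without a read in 1 group were bounded with 3 reads over the group, and those with 1 to 3 reads are given as ratios of pooled reads with an exact 95% interval. Libraries with the same number come from the same mouse by design, and their deviations from the group means correlated at 0.33, 0.35 and 0.30 over genes, so the mouse number pairs the samples. The blocked result is printed beside a result where it changed the call or moved a count by over 1.5 times (1135 genes higher and 1060 lower with the block). With 3 libraries against 3 and the pairing left out, the smallest p an exact permutation test can give is 0.1. A permutation test that keeps the pairs cannot go as low. Alternatives chosen before the data were examined were pseudocounts of 0.1 and 5 CPM, no filter and a filter of 5 CPM, upper-quartile rescaling, quantile normalization, eBayes without trend, array weights, the mouse as a block or as a random effect, and leaving out each library or mouse. Alternatives added after seeing the data were a pseudocount of 1 CPM, scaling to reads outside the MTRNR2L rows, voom on the recovered reads with and without the block, the block on 2 mice, and the block with fry or with camera at an estimated correlation.

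The fitting code was tested on simulated reads for the 13755 genes of the LSC and bulk comparison, with 200 genes changed by known folds. Without a mouse effect, the unblocked fit recovered 4.48% of 67 genes changed 2-fold, 65.7% of 67 changed 4-fold and 100% of 66 changed 16-fold, with 5 unchanged genes called. With a simulated mouse effect it recovered 0%, 16.4% and 98.5% with 0 unchanged genes called, and the blocked fit 2.99%, 74.6% and 100% with 6. A simulated list changed as a whole was called, and 0 of the other 19 were. Genes were simulated independently there, without a mouse effect. The list test was therefore not checked for lists whose genes are correlated. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.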

Results

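RNA from human leukemic cells grown in mice was sequenced. Acute myeloid leukemia (AML) had been produced in NSG mice, an immunodeficient strain, from human hematopoietic stem cells transduced with NPM1c, a mutant form of nucleophosmin that is displaced to the cytoplasm. Marrow of 3 mice, each from a separate transduction, was sorted into 2 populations: bulk leukemic cells, gated on GFP and CD33, and leukemic stem cells (LSC), gated on GFP, CD33 and CD123. GFP marked expression of NPM1c, CD33 is a myeloid surface antigen, and CD123 is the alpha chain of the interleukin 3 receptor. The bulk gate made no statement about CD123. Each population therefore had 3 libraries, and libraries with the same number came from the same mouse. The deposited table listed 13892 human gene symbols. It held 10669560 to 14933494 reads per library, of which 27.2% to 70.0% lay on 10 MTRNR2L rows, nuclear copies of mitochondrial ribosomal RNA. The share was highest in bulk replicate 1, where 3423878 reads remained for other genes, against 6132431 to 9571165 in the other libraries. A value of 3 reads corresponded to 0.514 CPM (reads scaled by library size) in bulk replicate 1 and to 0.190 to 0.254 CPM elsewhere. Such limits cover counting error only.

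The first comparison described how libraries differed by population and by mouse. Over the 13755 genes tested, 41.6% of the variance of log2 CPM lay between populations and 38.2% between mice, with 20.1% left over. These are shares of sums of squares, not adjusted for the number of groups. By chance alone 3 mice would take a larger share than 2 populations. The first principal component carried 45.9% of the variance and separated the bulk libraries, at -91.2 to -47.2, from the LSC libraries, at 39.8 to 126.6. LSC replicate 3 lay farthest out at 126.6. The second component carried 20.6% and set both libraries of mouse 3, each at 62.2, apart from the other 4 libraries, at -74.6 to 12.9. Granule genes followed this separation, and B lineage genes did not. Mean log2 CPM of 25 granule and neutrophil genes was 5.70 and 6.19 in bulk replicates 1 and 2 but 1.99 in bulk replicate 3. In the LSC libraries of mice 1, 2 and 3 it was 4.17, 4.26 and 1.17. Mean log2 CPM of 19 B cell and B progenitor markers was raised in bulk replicate 3 alone, at 6.38 against 3.75 and 3.80 in bulk replicates 1 and 2. It was 2.59 to 3.04 in the LSC libraries, lowest in LSC replicate 3. Differences between mice were described without a test.

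**Figure D1:**
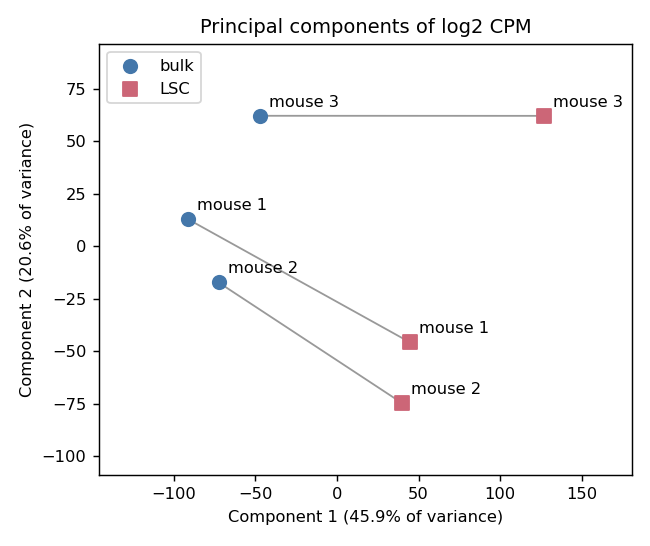
Principal components of log2 CPM over 13755 genes, with 1 point per library and lines joining the libraries of a mouse. The x axis is the first component (45.9% of variance) and the y axis the second (20.6%). Circles are bulk and squares LSC. Populations separate on the first component, and both libraries of mouse 3 lie at 62.2 on the second.

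The sort markers were examined next, since the gates name them. IL3RA, which encodes CD123, was far higher in the LSC libraries, at 108 ± 51.7 CPM against 2.01 ± 0.424 CPM in bulk (mean ± SD, n = 3). Its log2 change was 5.60 (SE 0.48, limma adjusted p = 0.000638), and it was higher in 3 of 3 mice. CD33 did not differ beyond the spread between replicates, with 5.34 ± 3.67 CPM in LSC and 8.57 ± 4.31 CPM in bulk, a log2 change of -0.96 (SE 0.76, adjusted p = 0.512). That value rested on mouse 3, without which it was 0.29 (adjusted p = 0.845). NPM1 stood at 419 ± 96.4 CPM in LSC and 811 ± 91.2 CPM in bulk, a log2 change of -0.97 (SE 0.28, adjusted p = 0.0879). With the mouse as a block the NPM1 difference passed the threshold (adjusted p = 0.00886), and it was lower in 3 of 3 mice. Reads of the transgene and of the resident gene share nearly all their sequence, so NPM1 values cannot be divided between them.

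**Figure D2:**
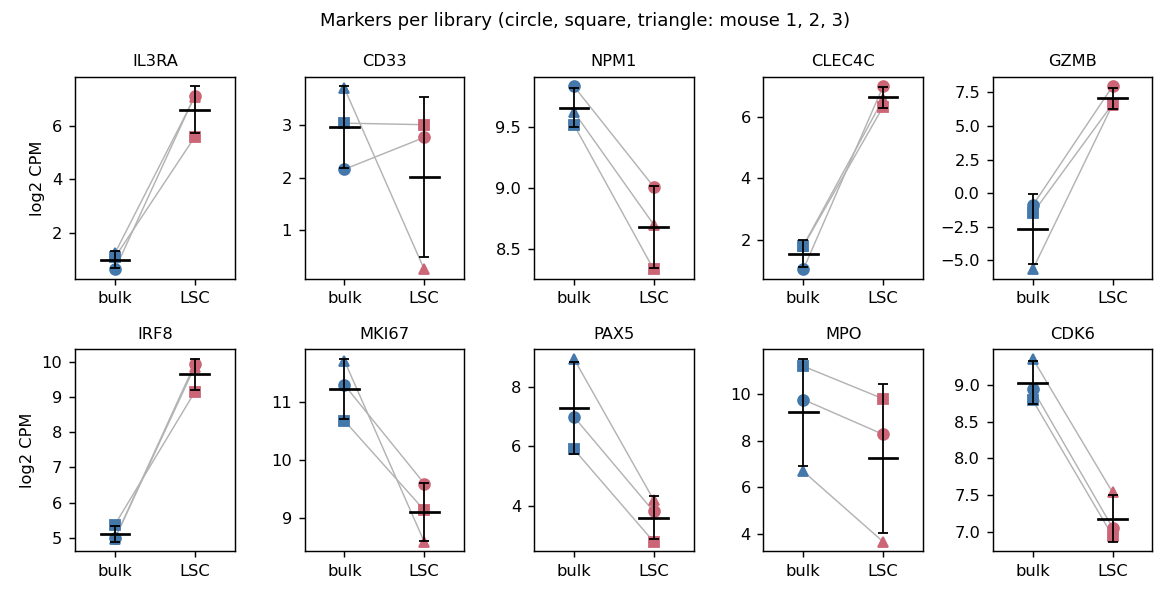
Log2 CPM of 10 genes in the bulk and LSC libraries, 1 panel per gene with its own scale. Points are libraries (circle, square and triangle for mouse 1, 2 and 3), grey lines join the libraries of a mouse, and black bars give the mean ± SD over 3 libraries. IL3RA, CLEC4C, GZMB and IRF8 lie higher in every LSC library than in every bulk library, MKI67, PAX5 and CDK6 lie lower, and CD33 overlaps.

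The populations were compared gene by gene with limma over 13755 genes, without the pairing by mouse. At an adjusted p of 0.05, 373 genes were higher and 183 lower in LSC than in bulk. All 373 and all 183 changed in their direction in each of the 3 mice. Selection on the same libraries makes that likely, so it is not separate support. The largest increases belonged to genes almost silent in bulk. LILRA4, a receptor of plasmacytoid dendritic cells, had 1 read over the 3 bulk libraries and 2398 over the 3 LSC libraries, a ratio of 1855 (95% exact counting interval 333 to 73304). Its adjusted p was 0.000605. Another 6 of the 12 genes with the largest increase had no read in bulk. EPHA2, an ephrin receptor, was at least 288-fold higher, the ligand gene WNT10A at least 212-fold, LOC101927921 at least 202-fold, NLRP7 at least 134-fold, the keratin gene KRT5 at least 113-fold and GRB14 at least 67.3-fold. These bounds set 3 reads over the bulk group as the floor, and the adjusted p ranged from 0.00109 for EPHA2 to 0.0108 for GRB14. TTC39A had 1 bulk read and a ratio of 518 (interval 92.7 to 20503). GZMB, which encodes granzyme B, rose from 0.284 ± 0.261 to 147 ± 86.6 CPM (log2 change 9.74, SE 1.11), and PTGDS, a prostaglandin D2 synthase, from 0.277 ± 0.189 to 79.2 ± 50.2 CPM. PACSIN1 and the ephrin receptor gene EPHB1 rose from 0.0922 ± 0.0962 to 36.5 ± 13.4 CPM and from 0.0991 ± 0.0883 to 27.9 ± 7.77 CPM. Fitted changes of such genes depend on the small prior in the deposited values.

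The 12 largest decreases were smaller in fitted log2 change than the 12 largest increases. PKLR, the pyruvate kinase of liver and red cells, had 238 bulk reads and 1 LSC read, a ratio of 308 (95% interval 54.7 to 12202, adjusted p = 0.0165). ABO, a glycosyltransferase gene, and the serotonin receptor gene HTR1F were lower by ratios of 129 (35.3 to 1075) and 200 (35.4 to 7964). EPCAM, an adhesion molecule of early erythroid and epithelial cells, fell from 9.73 ± 6.69 to 0.169 ± 0.240 CPM. The magnesium transporter gene SLC41A1 fell from 17.9 ± 5.69 to 0.577 ± 0.511 CPM (log2 change -5.28, SE 0.76, adjusted p = 0.00667). TGM2, a transglutaminase, fell from 15.8 ± 9.51 to 1.08 ± 0.963 CPM, and the imprinted gene PEG10 from 6.58 ± 3.50 to 0.327 ± 0.377 CPM. LOC100652999, UGT3A2, LCA5, the histone gene HIST1H2AG and PTTG2 completed the 12, with log2 changes of -6.78, -6.59, -6.41, -4.77 and -4.20. In the same order their calls were lost in 10, 10, 14, 6 and 12 of 27 settings. LOC100652999 had 270 bulk reads and 9 LSC reads, all in LSC replicate 2. UGT3A2 had 237 and 8, the latter all in LSC replicate 1. The fitted changes of these 2 genes depend on the small prior, and were as small as -1.21 and -1.10 in some setting. PTTG2 shares most of its sequence with PTTG1, and LILRA4, HIST1H2AG and ABO belong to families with similar members, so part of their reads could be assigned to relatives.

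The number of genes depended on the model and on single libraries. The unblocked test leaves the pairing by mouse out. Of the genes called, 67.1% were higher in LSC without the block and 51.7% with it. With the mouse as a block, 1135 genes were higher and 1060 lower, and these included all 373 and all 183. Without bulk replicate 1, bulk replicate 2, LSC replicate 1 or LSC replicate 3 the unblocked test called 204, 209, 168 and 197 genes higher and 38, 57, 91 and 50 lower. In the authors' deposited table no gene had a false discovery rate under 0.05 and the lowest was 0.0813. That table had 1723 genes at an unadjusted p under 0.05, and at a rate under 0.1 it had 103 genes higher and 8 lower in LSC. None of the 556 genes called here had the opposite direction in it, but its values come from the same libraries, so that is not separate support. Groups did not overlap for 3461 genes (25.2%), against 10% by chance for 3 libraries against 3.

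**Figure D3:**
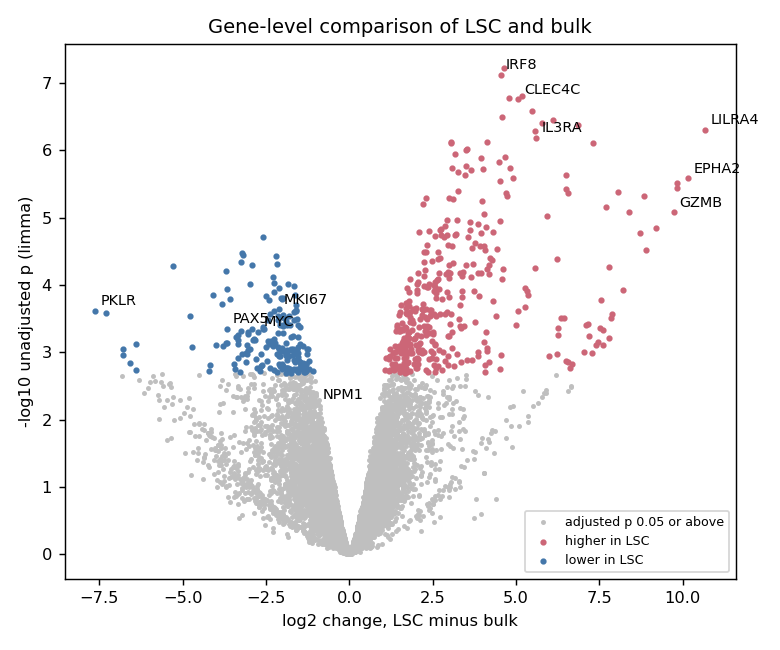
Each point is 1 of the genes tested, with its log2 change (LSC minus bulk) on the x axis and -log10 of the unadjusted limma p on the y axis. The 373 genes higher and the 183 genes lower in LSC at an adjusted p of 0.05 are coloured. The largest changes lie on the side of higher expression in LSC.

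Plasmacytoid dendritic cell markers formed the gene list with the largest change. Of 22 members, 19 were higher in LSC, none was lower, and 3 (MZB1, PLD4 and TCL1A) did not pass. MZB1 and PLD4 passed with the block. TCL1A is also on the B cell list. Adjusted over the list alone 21 were higher, and 21 with the mouse as a block. The median log2 change was 4.94, and 5.80, 4.91 and 4.91 in mice 1, 2 and 3. IRF8, a transcription factor of dendritic cell development, rose from 34.9 ± 5.73 to 826 ± 228 CPM (log2 change 4.54, SE 0.30, adjusted p = 0.00048). CLEC4C, the surface lectin BDCA-2, rose from 3.02 ± 0.832 to 101 ± 23.8 CPM. SERPINF1 rose from 2.29 ± 1.17 to 96.8 ± 18.1 CPM, and IGJ, the immunoglobulin joining chain, from 9.42 ± 5.02 to 628 ± 321 CPM. All 3 had an adjusted p of 0.00048 to 0.000587. Bulk libraries held 15 of the 22 members at a mean of 1 CPM or more. Camera placed the list above other genes (adjusted p = 9.97e-28), a call lost with an estimated correlation (adjusted p = 0.142). Conventional dendritic cell markers were not shifted (0 of 16 passed, median log2 change 0.56, adjusted p = 0.243), and their leading members LAMP3, CCR7, CLEC10A and CLEC9A had log2 changes of 1.42, 2.17, 1.24 and -2.20 with adjusted p of 0.148 or more. LAMP3, CCR7 and CLEC10A passed with the block. Changes were 0.80 for CLEC10A without bulk replicate 2 and -1.19 for CLEC9A without LSC replicate 3.

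Some genes of antigen presentation rose in LSC. In the MHC class II list 2 of 15 members rose, 3 when adjusted over the list alone, and all 15 had positive changes, with a median of 0.62. LGMN, an endosomal protease, rose from 7.89 ± 1.33 to 77.5 ± 23.7 CPM (log2 change 3.27, SE 0.34, adjusted p = 0.00145). CD74, the invariant chain, rose from 364 ± 80.0 to 900.4 ± 154 CPM (adjusted p = 0.0341). HLA-DMB and HLA-DPA1 had log2 changes of 2.10 and 1.22 and passed with the mouse as a block (adjusted p = 0.00451 and 0.00669). In the MHC class I list 1 of 17 members rose, 4 when adjusted over the list alone. It was B2M, the shared light chain, from 181 ± 66.4 to 985 ± 421 CPM (log2 change 2.41, adjusted p = 0.0176). HLA-B, HLA-F and TAP1 had log2 changes of 1.26, 1.82 and 1.21, and passed with the block. The block called 4 class II and 5 class I members higher. Camera adjusted p was 0.000109 for class II and 0.0492 for class I, and 0.406 and 0.542 with an estimated correlation. The class I call was lost under a filter of 5 CPM, other pseudocounts, and without bulk replicate 1 or 2, LSC replicate 3 or mouse 3, at an adjusted p of up to 0.362. HLA reads can be divided unevenly among similar alleles and genes.

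Camera placed interferon response genes and NF-kB and inflammatory genes above other genes (adjusted p = 0.022 and 0.00573). Both calls were lost with an estimated correlation (adjusted p = 0.494 and 0.406). Of 30 interferon response genes 5 rose and none fell, or 5 and 1 over the list alone, with a median log2 change of 0.27, and 0.39, 0.46 and 0.02 in mice 1, 2 and 3. The median was 0.13 without mouse 1 and 0.49 without mouse 3. They included IRF7, which is also on the plasmacytoid list and rose from 3.67 ± 0.903 to 113 ± 53.2 CPM. STAT2 rose from 63.4 ± 10.7 to 212 ± 53.0 CPM, IFI44 from 15.2 ± 4.66 to 132 ± 86.5 CPM and IFI44L from 31.3 ± 12.8 to 290 ± 188 CPM. Of 24 NF-kB and inflammatory genes 3 rose, 4 over the list alone, with a median of 0.46. These were NFKBIZ (log2 change 1.47, SE 0.26), the adaptor gene TRAF1 (2.43, SE 0.51) and TNFAIP3, an inhibitor of NF-kB signalling (1.64, SE 0.37). The adhesion gene ICAM1 had a change of 1.56 that did not pass (adjusted p = 0.0968) except with the block (0.0164). The block called 7 interferon genes higher and 2 lower, and 4 NF-kB genes higher and 1 lower. The interferon call was lost without LSC replicate 2 and without both libraries of mouse 2, with an adjusted p of up to 0.122. The NF-kB call was lost with the block on mice 1 and 2 (0.0647).

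Members of the interleukin 3 receptor and JAK-STAT list moved both ways. Of 25 members, IL3RA and CSF2RB rose, MYC fell and 22 did not pass. LSC were gated on CD123, so the rise of IL3RA follows from the sort, and the list was not tested without it. CSF2RB, the beta chain shared by the interleukin 3, interleukin 5 and GM-CSF receptors, rose from 27.9 ± 8.78 to 131 ± 45.9 CPM (log2 change 2.21, adjusted p = 0.0142). CSF2RA stood at 57.5 ± 18.6 and 127 ± 20.4 CPM (adjusted p = 0.0776, 0.0133 with the block). Over the list alone 3 rose and 1 fell, and with the block 7 rose and 1 fell. The list itself was not shifted (camera adjusted p = 0.0646, 0.542 with an estimated correlation). It was called with the mouse as a block (0.0303) and without bulk replicate 1 or 2, LSC replicate 3 or mouse 3 (0.00746 to 0.0375), and in 10 of 25 settings in all. The median was 0.33. In the unfolded protein and heat shock list 4 of 28 members rose, 4 over the list alone with 1 lower, and 5 with the block with 4 lower. Among them HERPUD1 rose from 17.8 ± 1.68 to 208 ± 73.1 CPM, ERN1 from 4.95 ± 1.68 to 42.8 ± 7.64 CPM, DNAJB9 from 5.84 ± 2.47 to 33.7 ± 14.1 CPM and PDIA4 from 21.4 ± 11.9 to 81.0 ± 14.2 CPM. Their adjusted p lay between 0.00104 and 0.0309, while the whole list was not shifted (median 0.11, camera adjusted p = 0.314), except without bulk replicate 1 (0.0455).

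Some proliferation genes fell in LSC. Of 35 genes of the G2 and M phases 12 fell, none rose and all 35 had negative changes, with a median log2 change of -1.68. Adjusted over the list alone 29 fell, and 28 with the mouse as a block. MKI67, the proliferation antigen Ki-67, fell from 2510 ± 864 to 573 ± 194 CPM (log2 change -2.13, SE 0.37, adjusted p = 0.0161). CENPF fell from 1199 ± 488 to 234 ± 47.6 CPM, TOP2A, a DNA topoisomerase, from 866 ± 404 to 205 ± 43.1 CPM and HMMR from 189 ± 45.0 to 40.4 ± 8.23 CPM. In S phase 5 of 37 genes fell, with a median of -1.29. The count was 18 over the list alone and 19 with the block. EXO1, CLSPN, DTL and the helicase subunit gene MCM4 had log2 changes of -2.25, -1.61, -1.57 and -1.56, with adjusted p of 0.0109 to 0.0214. Replication-dependent histone genes fell in 6 of 19 cases, 14 over the list alone and 13 with the block, with a median of -2.92. HIST1H3B fell from 62.2 ± 35.3 to 6.96 ± 3.61 CPM, HIST1H2BF from 32.6 ± 26.3 to 2.53 ± 0.976 CPM and HIST1H2BH from 8.58 ± 1.85 to 0.955 ± 0.768 CPM. Camera adjusted p was 9.16e-20, 8.94e-13 and 4.69e-11 for the G2 and M, S phase and histone lists. With an estimated correlation the adjusted p was 0.215, 0.0526 and 0.177.

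Few growth and chromatin genes passed the unblocked test. In the list of MYC targets and ribosome biogenesis 2 of 31 members fell, 6 over the list alone and 9 with the block, with a median of -0.40. MYC itself fell from 67.0 ± 21.6 to 11.2 ± 6.87 CPM (log2 change -2.75, SE 0.53, adjusted p = 0.0235) and NCL, nucleolin, from 2907 ± 816 to 894 ± 273 CPM. NOP58 and WDR43 had changes of -1.35 and -1.32 that passed with the block. Of 34 epigenetic regulators recurrently mutated or targeted in AML 1 fell, 4 over the list alone and 9 with the block, with a median of -0.41. EZH2, the Polycomb methyltransferase, fell from 108 ± 16.6 to 44.6 ± 11.3 CPM (adjusted p = 0.0466). DNMT1, DNMT3B and SMC1A had log2 changes of -1.52, -2.13 and -1.34, and passed with the block. Camera adjusted p was 0.0034 and 0.000398 for these lists, and 0.542 and 0.35 with an estimated correlation.

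Genes tied to stemness were not higher in LSC as lists. Of 13 measured members of the LSC17 stemness score 1 fell and none rose, with a median log2 change of -1.24, 3 lower over the list alone and 4 with the block. CDK6 fell from 532 ± 113 to 147 ± 33.7 CPM (log2 change -1.86, SE 0.29, adjusted p = 0.00944). CD34, the stem and progenitor antigen, stood at 17.1 ± 9.81 CPM in bulk and 3.12 ± 2.33 CPM in LSC (log2 change -2.66, adjusted p = 0.096, 0.0361 with the block), and NGFRAP1 at 2.63 ± 0.585 and 0.341 ± 0.296 CPM (adjusted p = 0.164). The call for the list (camera adjusted p = 0.00616, 0.406 with an estimated correlation) was lost without bulk replicate 3 (0.0567). Among 24 stem and progenitor transcription factors MYB fell from 615 ± 94.4 to 221 ± 100.3 CPM (adjusted p = 0.0366), and 3 were lower over the list alone. With the block 2 were higher and 7 lower. ERG, GFI1B and HMGA2 had log2 changes of -2.54, -3.88 and -1.51, and passed with the block. The median was -0.85, with a camera adjusted p of 0.0125 and, with an estimated correlation, 0.406. That call was lost without bulk replicate 1 (0.0598) and under a filter of 5 CPM (0.0665). Of 22 leukemic stem cell surface markers LILRB4 rose from 14.9 ± 6.44 to 57.5 ± 14.3 CPM and 21 did not pass. PROM1, ITGA6 and KIT had log2 changes of -5.91, -1.69 and -2.42, and passed with the block. Over the list alone 2 were higher and 4 lower, and with the block 3 and 6. The median of 0.01 was positive, while the mean of -0.55 and the camera direction were negative (adjusted p = 0.505). In the HOX list 7 of 23 members were measured and HOXB2 rose from 0.512 ± 0.257 to 6.44 ± 4.49 CPM (adjusted p = 0.0392, 1 over the list alone). HOXA9, often high in NPM1-mutant AML, stood at 1.92 ± 0.138 CPM in bulk and 0.391 ± 0.367 CPM in LSC (adjusted p = 0.236), and HOXB3 had a log2 change of 1.74 that did not pass. Several of these changes kept their direction but were smaller without 1 mouse. Without mouse 3 they were -1.54 for ERG, -1.41 for CD34, -3.90 for PROM1 and -2.36 for NGFRAP1, and without mouse 2 they were -1.77 for HOXA9 and 0.89 for HOXB3. The HOX list was not shifted (median -0.97, mean -0.36, camera direction upward, adjusted p = 0.917).

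Markers of other blood lineages were examined because the gates could hold them. Of 26 erythroid and megakaryocyte markers 3 fell, 4 over the list alone and 14 with the mouse as a block, with a median log2 change of -2.08. Among them CA1, a carbonic anhydrase, fell from 24.3 ± 14.9 to 2.04 ± 1.31 CPM and HBB from 57.4 ± 9.28 to 12.8 ± 8.47 CPM, with adjusted p of 0.0128 and 0.0289. Of 19 B cell and B progenitor markers 3 fell, with 10 lower and 1 higher over the list alone, 9 and 1 with the block, and a median of -2.03. PAX5, the B lineage factor, fell from 226 ± 232 to 13.2 ± 5.80 CPM, EBF1 from 107 ± 122 to 6.99 ± 2.55 CPM and CD24 from 583 ± 361 to 135 ± 53.3 CPM. The wide spread in bulk came from bulk replicate 3, with 491 CPM of PAX5 against 127 and 59.9 in bulk replicates 1 and 2, and 248 CPM of EBF1 against 46.1 and 26.8. Without mouse 3 the log2 changes of EBF1 and CD24 were -2.08 and -1.19 (adjusted p = 0.059 and 0.132). The list median was -1.05, -1.41 and -3.68 in mice 1, 2 and 3. None of 25 granule and neutrophil genes passed, nor over the list alone, and 8 fell with the block, among them CSF3R (log2 change -2.05, adjusted p = 0.221 and with the block 0.0016, and a change of -1.14 without LSC replicate 3). The granule median was -1.39, and -1.49, -2.07 and -0.17 in mice 1, 2 and 3. Camera adjusted p was 1.26e-05, 5.63e-05 and 0.0135 for the erythroid, B and granule lists, and 0.406, 0.542 and 0.765 with an estimated correlation. The granule call was lost without bulk replicate 1, bulk replicate 2 or LSC replicate 3 and without mouse 1 or mouse 2, at an adjusted p of up to 0.365.

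Monocyte, mast cell and T cell lists were not shifted. In the monocyte and macrophage list 2 of 21 members rose and 1 fell, with a median of -0.52 and a camera adjusted p of 0.314. CCR2, a chemokine receptor, rose from 7.90 ± 3.73 to 70.2 ± 9.02 CPM and MS4A6A from 37.3 ± 12.8 to 151 ± 20.3 CPM, whereas VCAN fell from 766 ± 224 to 156 ± 114 CPM (log2 change -2.62, and -1.63 without mouse 3). LYZ, lysozyme, stood at 3660 ± 1034 and 1370 ± 734 CPM (adjusted p = 0.0805, 0.0053 with the block). In the basophil, mast cell and eosinophil list SIGLEC6 rose from 2.33 ± 0.994 to 21.9 ± 4.84 CPM and CCR3 from 0.363 ± 0.311 to 9.63 ± 4.95 CPM. The other 20 of its 22 members did not pass, and the list median was -0.19 (camera adjusted p = 0.761). In the T cell and NK cell list 1 of 15 members rose. It was CD4 (log2 change 2.31, adjusted p = 0.0101), and the list had a median of 0.18 (camera adjusted p = 0.505). Over each list alone the counts were 2 higher and 3 lower for monocytes, 2 and 1 for mast cells, and 1 and 0 for T cells. With the block they were 2 and 8 for monocytes and 3 and 8 for mast cells.

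**Figure D4:**
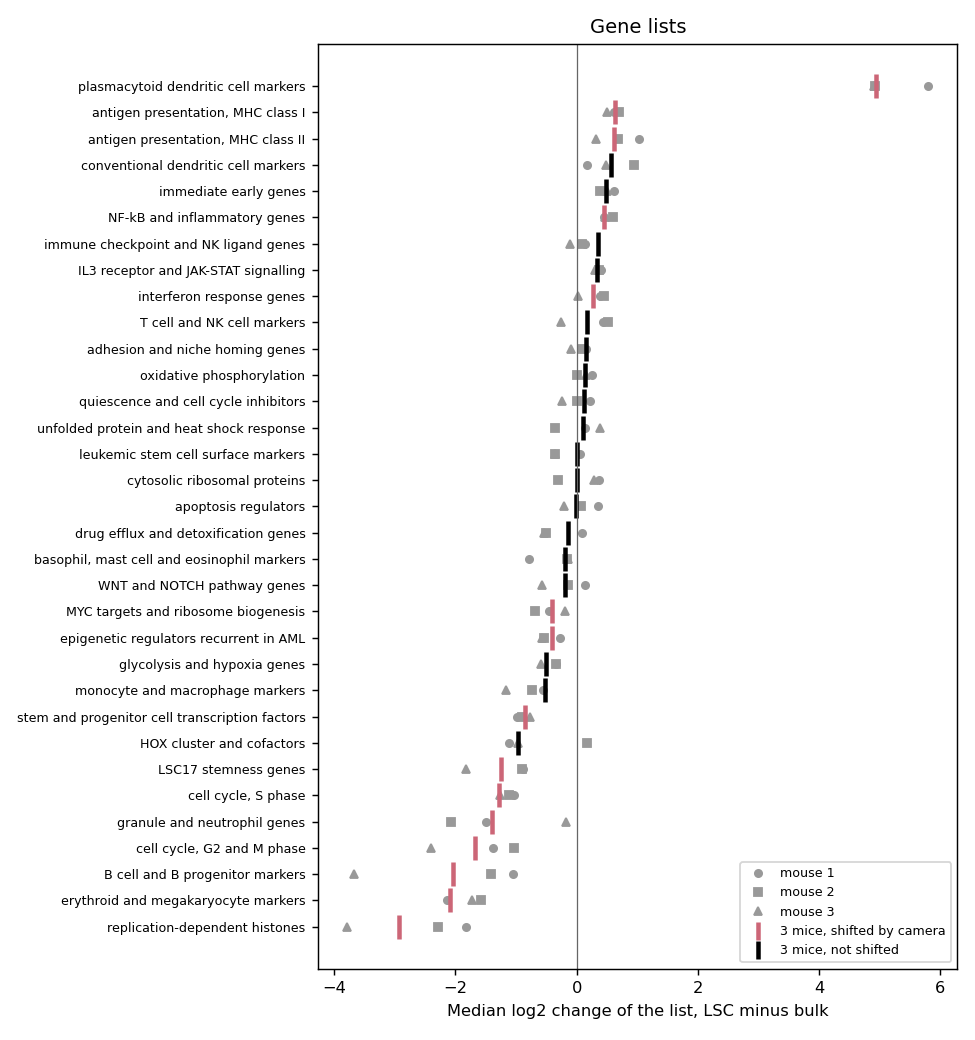
Median log2 change (LSC minus bulk, x axis) of each of the 33 gene lists tested. Vertical bars give the median of the changes fitted over 3 mice, red where camera called the list shifted, and grey symbols give the median within each mouse. Plasmacytoid dendritic cell markers lie at 4.94 and replication-dependent histones at -2.92.

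Over the 33 lists tested, camera called 15 shifted, 5 toward higher and 10 toward lower expression in LSC. Every other split of the 6 libraries 3 against 3 called 6 to 15 lists. The number of list calls therefore does not by itself set LSC apart from bulk. With an estimated correlation 0 lists remained called, and 4 had an unadjusted p under 0.05. Fry, which tests whether the genes of a list move on balance one way without comparing them to other genes, called 4 lists, namely plasmacytoid dendritic cell markers, S phase, G2 and M phase and histones. With the mouse as a block fry called 5. Plasmacytoid markers and S phase were again called (adjusted p = 0.0356 for each), and G2 and M phase and histones were not (0.0936 and 0.0754). Stem and progenitor factors (0.0356), MHC class I (0.0356) and epigenetic regulators (0.0485) were added. Leaving out 1 library or mouse also moved medians of other shifted lists by more than 1.5 times. The median reached -1.89 for LSC17, -1.10 for B markers, -1.29 for erythroid markers, 0.40 for MHC class II, 0.33 for MHC class I and 0.70 for NF-kB. It ranged from -2.73 to -0.21 for granule genes and from -0.73 to -0.25 for MYC targets. A pseudocount of 5 CPM, which shrinks changes of low genes by construction, brought it to -1.29 for histones, 3.04 for plasmacytoid markers, -0.78 for S phase, -0.41 for stem and progenitor factors, -0.51 for LSC17 and -0.98 for erythroid markers. With 1 CPM it was -1.76 for histones.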

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

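Alternatives named in processing as added, with pseudocount 1, MTRNR2L-free scaling, voom, the block on 2 mice, or the block with fry or an estimated correlation, were chosen after seeing the data. The main counts were 373 genes higher and 183 lower in LSC. With the replicate block they were 1135 and 1060, with the mouse as a random effect 1090 and 983, with the block and upper-quartile rescaling 1054 and 1193, with the block and quantile normalization 1140 and 1205, and with voom and the block 1216 and 1217. With the block on 2 mice, 344 genes were lower without mouse 1 and 296 without mouse 2, and 1747 were higher and 1567 lower without mouse 3. Without the variance trend 197 were higher and 54 lower. Array weights gave 282 lower, and pseudocounts of 5 and 1 CPM gave 280 and 302. Leaving out a library or mouse gave 37 to 346 higher and 0 to 169 lower. The count of 0 was limma's without mouse 1, where 1728 genes had an unadjusted p under 0.05 and the block called 344 lower. Fewer samples were tested there, and for the other shifts the cause was not tested. Each other setting stayed within 1.5 times.

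With limma and with camera at the preset correlation the block on all 3 mice ended no call, and it changed no call other than those given beside results. The 15 shifted lists became 0 with an estimated correlation, with or without the block. Fry, which asks another question, called 4, or 5 with the block, and 14 to 17 were called elsewhere. Among the 15 the correlation estimated without the block ran from 0.00862 for S phase to 0.732 for granule genes, against the preset 0.01. It was 0.644 for B markers, 0.269 for plasmacytoid markers and 0.264 for G2 and M. Where such estimates hold, camera p-values at the preset are too small. Of the 15, 9 were called in the same direction in all 25 settings. MHC class I, granule, interferon, LSC17, NF-kB and stem cell factor lists each lost the call somewhere. Camera's direction changed in 30 combinations of list and setting over 7 lists, 0 of them called. IL3RA passed in all 28 settings (log2 change 3.87 to 6.15, adjusted p up to 0.0408). CD33 ranged from -1.75 to 0.29 without 1 library or mouse, and the change was 0.29 without mouse 3, with or without the block, and the cause was not tested. NPM1 passed with the block (-0.97), the random effect (-0.97), quantile normalization (-0.78), the block with quantile normalization (-0.78) or upper-quartile rescaling (-1.02), voom and the block (-0.97), and the block without mouse 3 (-1.001), and ranged from 0.318 to 4.68e-05 in adjusted p. Of 85 named genes past the threshold none changed direction and 12 passed in all 28 settings. The variance share between mice was 38.2% and moved to 38.7%, 39.0%, 38.1%, 38.6%, 38.4% and 37.5% with pseudocounts of 0.1 and 5, no filter, a 5 CPM filter, upper-quartile rescaling and quantile normalization. A count model was not run, since the deposited unit is log2, and TMM scaling was replaced by upper-quartile rescaling. Lists could not be tested with a random effect. Depth limits genes under 0.514 CPM in bulk replicate 1.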

Other observations

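All tests of explanations below, and their bounds, were set after the values were seen, except the regrouping of libraries. The lists were fixed earlier, but members of the next 4 were picked for mention after their values were seen. Further gene groups not described above moved in part. Of 29 immediate early genes 3 rose and 1 fell (camera adjusted p = 0.0646, 0.764 with an estimated correlation, median log2 change 0.49, 4 higher and 1 lower over the list alone). The phosphatase gene DUSP5 rose from 1.05 ± 0.589 to 109 ± 91.8 CPM (SD, n = 3, limma adjusted p = 0.00104), BTG2 from 40.0 ± 2.51 to 195 ± 66.7 CPM, and KLF6 by a log2 change of 1.42, and MYC fell. With the mouse as a block that list was called shifted (adjusted p = 0.0305), with 6 members higher and 2 lower. It was also called without bulk replicate 1, LSC replicate 2 or LSC replicate 3 (0.00158, 0.0455 and 0.00544) and under a filter of 5 CPM (0.0478). Among 21 quiescence genes and cell cycle inhibitors BTG2 and CDKN1A, the p21 inhibitor, rose and FOXO1 fell. CDKN1A went from 4.75 ± 2.42 to 51.3 ± 29.9 CPM and FOXO1 from 52.0 ± 52.4 to 4.67 ± 1.32 CPM (list median 0.12, camera adjusted p = 0.736, 2 and 1 over the list alone). The FOXO1 mean rested on bulk replicate 3, with 112 CPM against 24.8 and 18.8 in bulk replicates 1 and 2, and its log2 change was -3.04, or -2.01 without mouse 3. In the WNT and NOTCH list NOTCH4 rose from 0.915 ± 0.246 to 19.6 ± 14.3 CPM, DTX4 from 5.70 ± 1.55 to 42.1 ± 1.13 CPM and FZD3 from 13.7 ± 2.26 to 48.1 ± 9.54 CPM, while LEF1 fell from 79.4 ± 85.0 to 6.49 ± 1.60 CPM (25 tested, median -0.20, adjusted p = 0.736, 3 and 3 over the list alone). LEF1 too was highest in bulk replicate 3, with 177 CPM against 36.6 and 24.2. In the drug efflux and detoxification list GPX1 rose from 5.74 ± 0.849 to 43.3 ± 21.7 CPM and SLC7A11 from 21.1 ± 8.99 to 95.2 ± 43.5 CPM. ABCG2 stood at 4.32 ± 0.316 and 0.467 ± 0.444 CPM and passed with the block (26 tested, median -0.15, adjusted p = 0.604, 4 and 3 over the list alone). Median changes of the remaining lists, none of them shifted, were 0.35 for immune checkpoint and NK ligand genes, 0.14 for oxidative phosphorylation, -0.51 for glycolysis and hypoxia, 0.01 for cytosolic ribosomal proteins, -0.01 for apoptosis regulators and 0.15 for adhesion and niche homing genes, with camera adjusted p of 0.505, 0.314, 0.314, 0.58, 0.604 and 0.94. The ribosomal list was called without mouse 2 (0.0194, and 0.0149 with the block). Camera placed apoptosis regulators upward, against their median and mean of -0.04, and adhesion genes downward with their mean of -0.26. In these lists CD24 fell and EGLN3, an oxygen-sensing hydroxylase, rose from 2.15 ± 1.20 to 41.6 ± 19.4 CPM, and no other member passed. Adjusted over the list alone 1 checkpoint gene was lower, 1 glycolysis gene higher, and 3 adhesion genes were higher and 3 lower. The block called higher and lower members in quiescence (3 and 1), WNT and NOTCH (3 and 4), efflux (3 and 4), checkpoint (2 and 2), oxidative phosphorylation (3 and 1), glycolysis (3 and 7), ribosomal (5 and 1) and adhesion (3 and 4) lists.

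Genes named here were chosen after their values were seen. The nucleic acid receptor genes TLR7 and TLR9 rose from 13.1 ± 12.1 to 190 ± 53.2 CPM and from 8.61 ± 10.3 to 100.1 ± 62.7 CPM (limma adjusted p = 0.00571 and 0.0235). The transcription factor genes RUNX2 and BCL11A, both active in plasmacytoid dendritic cells, rose from 31.1 ± 4.38 to 538 ± 246 CPM and from 57.8 ± 25.5 to 259 ± 24.1 CPM. AXL, a receptor tyrosine kinase that marks a dendritic cell subset together with SIGLEC6, rose from 6.78 ± 3.57 to 40.6 ± 24.0 CPM (adjusted p = 0.0382). MPO, myeloperoxidase, was at 871, 2344 and 103 CPM in bulk replicates 1, 2 and 3 and at 309, 890.4 and 12.7 CPM in LSC replicates 1, 2 and 3. EPX, eosinophil peroxidase, was at 94.9, 530.5 and 1.79 CPM in the bulk libraries. MPO and EPX passed with the mouse as a block (adjusted p = 0.00432 and 0.000301, against 0.496 and 0.449).

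Plasmacytoid dendritic cell markers were higher by list median in the LSC libraries of every mouse, with 19 of 22 members past the threshold. The list call was lost with an estimated correlation (camera adjusted p = 0.142). Plasmacytoid dendritic cells carry CD123 at high levels, and the GFP and CD33 gates would remove cells that lack the transgene or CD33. A minor share of such cells (below 50% of RNA, by definition of minor) added to otherwise bulk-like cells would lower no gene by more than 1 on the log2 scale. Limma's treat found 6 genes lower by more than that at an adjusted p of 0.05, and 60 with the mouse as a block. That argues against a minor share as the only difference from bulk. It does not weigh on a minor share among cells that differ from bulk in other ways. The CD123 gate could by itself lower genes of cells it leaves out. Shallow bulk libraries are argued against by mouse 3, whose bulk library was deeper than its LSC library and whose list median was 4.91, while 15 of the 22 members averaged 1 CPM or more in bulk. Whether the transcripts may come from dendritic cells without the mutant gene or from leukemic cells expressing this programme cannot be told apart, since NPM1 reads (log2 change -0.97) do not separate the mutant from the normal gene. Other sources were not tested, so these need not be the only ones.

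The G2 and M list had median changes of -1.38, -1.04 and -2.40 in mice 1, 2 and 3, with 12 of 35 members past the threshold, and its call and those of the S phase and histone lists were lost with an estimated correlation (adjusted p = 0.215, 0.0526 and 0.177). Scaling between libraries is argued against as the whole cause, since under quantile normalization the G2 and M list stayed at -1.64 relative to the median of all genes. Dilution of cycling bulk-like cells by a non-cycling share below 50% could lower a gene by up to 1. Of the 91 members of the G2 and M, S phase and histone lists, 69 had a fitted change below -1. Treat found 7 lower by more than 1 when adjusted over them alone but 0 when adjusted over all genes. With the mouse as a block these counts were 18 and 7. The histone median was -1.83, -2.28 and -3.78 in mice 1, 2 and 3, and -1.29 over all mice with a pseudocount of 5 CPM. That argues against dilution as the whole cause for the histone genes. For the G2 and M and S phase lists this cannot be told, since the treat count over all genes depended on the block. A larger share of other cells and a lower rate of cycling in the sorted cells stay open, untested.

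Bulk replicate 3, sorted with a GFP and CD33 gate that would remove B cells lacking the transgene or CD33, had fewer granule and more B lineage transcripts than bulk replicates 1 and 2. Dilution by a share of B lineage cells below 50% is argued against as the source of the fewer granule transcripts. The granule list was lower by a median of -4.34 on the log2 scale, where such dilution of cells like those of the other bulk libraries allows -1. The other bulk replicates differed by -0.52. A fault of bulk replicate 3 alone is argued against for the granule genes, since LSC replicate 3 was lower than LSC replicates 1 and 2 by a median of -2.73. Because granule genes were low in both libraries of mouse 3, they do not weigh on a B lineage share as the source of the raised B markers. All 19 B markers were higher in bulk replicate 3 by more than 1, with a median of 2.52, against -0.28 in LSC replicate 3. No biological explanation was tested, nor why B markers were raised in 1 library of that mouse and not in the other.

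Among the 10 ways to split the 6 libraries 3 against 3, the real split called 556 genes and the highest other 0, although the other splits had 58 to 1019 genes at an unadjusted limma p under 0.05. That was 1 of 10 splits. For lists the real split called 15 and the other splits 6 to 15, so 2 of 10 splits gave as many. With 10 splits no share under 0.05 is possible. Of the 4 splits that part all 3 pairs, the 3 others called 8 to 10 lists. The split with 15 lists set bulk replicate 1 and LSC replicates 1 and 2 against the rest and parts 1 pair. Why it called as many was not tested.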
